A study of Mus musculus with 5 samples.

How the data were processed

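Small RNA sequencing was read for 5 libraries of the mouse OP9 line, a bone-marrow-derived stromal line that can form adipocytes. All were collected at day 10 of adipogenic differentiation under 1 µM rosiglitazone, an agonist of the nuclear receptor PPARγ. The labels put 2 libraries in the Drosha knockout group and 3 in the empty-vector group. Per the labels' protocols, unique molecular identifiers were built into the libraries and sequencing was on a DNBSEQ instrument. How the identifiers were used in counting is not given in the sources used here. Nothing in the labels says that replicates came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

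The authors deposited TPM values (reads divided by length and scaled) for 1191 pairs of a mature miRNA and its precursor, with the same sum in each library. Bowtie2 2.5.1 and build GRCm38 are named per the submitters' processing notes, which give no role for either. The counting tool, trimming, filters and use of strand are not given in the sources used here. The table held 1105 mature miRNAs from 1058 precursors, of which 816 had names ending in 5p, 126 ended in 3p and 163 carried no arm. Both mature arms were listed for 133 precursors, so many 3p arms were not analysed here and several families are represented by 5p arms, which for some of them are the passenger strand. The Drosha transcript was not analysed here either. For 50 mature miRNAs several precursors were listed (136 pairs), and a read matching several precursors was counted at each. The pair with the highest mean was used for each mature miRNA.

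TPM divides reads by a length, and whole reads were recovered from the values. For each pair a length between 15 and 30 bases was searched at which every value was a whole number of reads within 1e-06. Lengths of 16 to 27 bases were found, 100% of values came out whole, and 6 of 536 pairs with reads had more than 1 possible length. Recovered totals were 304722 and 277142 reads in the knockout libraries and 2262367, 2028962 and 1918589 in the empty-vector libraries. They count a read at each listed precursor that it matched, and do not count all reads sequenced. With 1 pair per mature miRNA the totals were 214264 and 200659 in the knockout libraries. They were 1613590, 1466826 and 1347800 in the empty-vector libraries. At a length of 22 bases, 1 read was worth 3.32 and 3.67 TPM in the knockout libraries and 0.448, 0.499 and 0.528 TPM in the empty-vector libraries. A count of 0 allows up to 3 reads, or 9.95 and 11.0 TPM in the knockout libraries and 1.34, 1.50 and 1.58 TPM in the others. These floors cover counting error only.

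Group comparisons used limma 3.58.1 in R 4.3.3 on log2(TPM + 1) with a mean-variance trend, for the 205 miRNAs with a mean of at least 5 TPM over the 5 libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method (BH) with a threshold of 0.05. The fit had 3 residual degrees of freedom and 24.2 prior degrees of freedom. Fold changes on this scale understate the change of low miRNAs, and folds printed as such are ratios of mean TPM. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with BH adjustment over the lists. They were also tested with fry, whose p-values were not adjusted. Values computed once per library were compared by two-sided exact permutation tests over the 10 splits of 2 against 3, which cannot give a p below 0.2.

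The test, the lists and the rule for named miRNAs were fixed before the data were examined. The named miRNAs were those in the series title; the 10 largest rises and 10 largest falls past the threshold with a mean of at least 100 TPM and no overlap between the groups' libraries; the 5 most abundant in the empty-vector group; every detected Drosha-independent list member; and up to 4 called members of largest change per other list, or the 2 most abundant members where none was called. The lists were Drosha-independent miRNAs, miR-204 and miR-211, the miR-15/16, let-7, miR-29, miR-30 and miR-181 families, pro-adipogenic and anti-adipogenic miRNAs, the miR-17~92 and paralogue clusters, the miR-232724 clusters, mesenchymal miRNAs, the Dlk1-Dio3 and Sfmbt2 clusters, and marker miRNAs of haematopoietic, epithelial, muscle, neural and liver, and endothelial cells.

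The procedure was tested on simulated reads drawn from the means and library sizes of this comparison with 60 changed miRNAs in each of 20 draws and a dispersion of 0.03, with a median of 225 tested. Changes of 1 on the log2 scale were recovered in 67.5% of cases and changes of 2 in 92.2%, while 2.33% of unchanged miRNAs were called and 7.44% of calls were false. Only miRNAs with a mean under 10000 TPM were changed, rises and falls were balanced, and both groups had the same dispersion. These rates may therefore not hold where most changes go in 1 direction or the groups differ in spread. Hairpin positions came from a RefSeq gene table for GRCm38 and host genes from GENCODE M21, and 462 of 471 miRNAs with reads were placed. A hairpin was called a mirtron where both its ends lay within 10 bases of the ends of an intron. In 4 groups holding 8 miRNAs all libraries had identical values, so these miRNAs share reads.

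Alternatives were other pseudocounts, other filters on low values, rescaling by trimmed means (TMM), by median of ratios or by the summed Drosha-independent list, quantile normalization, robust empirical Bayes, a block on the replicate number and leaving out each library. Without a knockout library that group has 1 library, which limma then assumes to vary like the empty-vector libraries. After the data were seen, limma-voom on the recovered reads, thinning every library to 277142 reads, the use of every mature-precursor pair and, for a test of hairpin positions, a filter on the empty-vector mean were added. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the values and figures.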

Results

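Small RNAs were sequenced from OP9 cells, a mouse bone-marrow stromal line, at day 10 of adipogenic differentiation under rosiglitazone. The design compared 2 libraries from cells with a knockout of Drosha, the nuclear RNase III enzyme that cuts primary miRNA transcripts into hairpins, with 3 libraries from empty-vector cells. The deposited TPM values gave 471 mature miRNAs with reads. Recovered reads, with a read counted at each matching precursor, averaged 290932 per knockout library and 2069973 per empty-vector library, a 7.11-fold difference. Low miRNAs were therefore measured less precisely in the knockout. Across tested miRNAs, the correlation of log2 values was 0.956 between the knockout libraries, 0.987 to 0.989 between empty-vector libraries and 0.882 to 0.930 between groups. These correlations are across miRNAs, which are not independent replicates. TPM is relative to all listed miRNA reads, so every rise or fall given here is a change in relative abundance.

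The first question was whether miRNAs that are made without Drosha behaved apart from the rest, which also checks the group labels because the Drosha transcript was not analysed here. All 4 tested members of the Drosha-independent list rose in the knockout. miR-484, which comes from a capped short precursor, rose 5.21-fold. It was at 21326 ± 446 TPM (SD, n = 2) in the knockout and 4094 ± 877 TPM (SD, n = 3) in the empty-vector group. The mirtron miR-1981-5p, released by splicing, was at 5181 ± 992 against 591 ± 33.9 TPM, an 8.76-fold rise. Another mirtron, miR-877-5p, was at 390 ± 78.1 against 17.5 ± 7.97 TPM, a 22.3-fold rise, and miR-1839-5p, from a small Cajal body RNA, was at 125 ± 5.92 against 56.5 ± 16.1 TPM. miR-702-5p had 1 read, in knockout library 1, and was not tested.

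In limma with BH adjustment, the log2 changes were 2.40 (SE 0.23, adjusted p = 1.78e-09) for miR-484, 3.12 (SE 0.24, adjusted p = 4.81e-11) for miR-1981-5p, 4.50 (SE 0.43, adjusted p = 1.82e-09) for miR-877-5p and 1.17 (SE 0.37, adjusted p = 0.0107) for miR-1839-5p. Each was higher in both knockout libraries than in any empty-vector library, and 4 were also higher when adjusted over the list alone. On GRCm38, Mir484 lies on chromosome 16 at 14159626 to 14159692, antisense to Marf1. Mir1981 lies in an intron of Marc2 on chromosome 1 at 184822407 to 184822488. Mir877 lies in an intron of Abcf1 on chromosome 17 at 35960730 to 35960814, and Mir1839 lies on chromosome 7 at 81529916 to 81529988. The list's median log2 change was 2.76, with a camera adjusted p = 0.000389, but adjusted p = 0.391 with an estimated correlation. The list took 2.70% ± 0.046 (SD, n = 2) of TPM in the knockout and 0.476% ± 0.0847 (SD, n = 3) in the empty-vector group, a 5.68-fold difference whose exact permutation p was 0.2, the smallest that 2 against 3 allows.

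**Figure D1:**
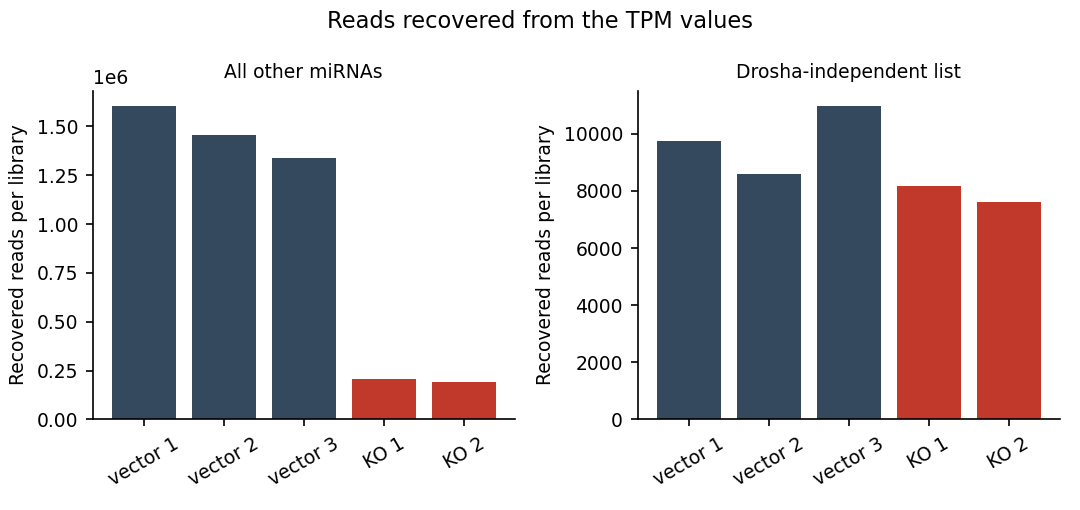
Whole reads recovered per library (bars) for all other miRNAs (left) and the Drosha-independent list (right), at the pair used for each mature miRNA. Each panel has a separate linear axis from 0. Other miRNAs ranged from 193063 to 206105 reads in the knockout and from 1336840 to 1603840 in the empty-vector libraries, while the list ranged from 7596 to 8159 and from 8575 to 10965.

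The call for miR-1839-5p was lost without knockout library 1 (log2 change 1.12), knockout library 2 (1.22) or empty-vector library 1 (0.99), under TMM rescaling (0.79), and after thinning to equal reads (0.77). With libraries rescaled to an equal sum of the list, miR-484 (-0.12) and miR-1839-5p (-1.32) turned negative and the call of miR-1981-5p (0.60) was lost, while that of miR-877-5p (2.04) was kept. That sum was mostly miR-484. Without it the list took 0.570% of TPM in the knockout and 0.0665% in the empty-vector group. This rescaling holds the list's sum equal by construction, so it cannot test whether the list rose.

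The series title names miR-204 and miR-15b, and both fell in the knockout. miR-204-5p, a miRNA that targets the osteogenic factor Runx2, was at 171 ± 44.6 TPM (SD, n = 2) in the knockout and 2911 ± 1196 TPM (SD, n = 3) in the empty-vector group, 17.0-fold lower. miR-15b-5p, of the growth-restraining miR-15/16 seed family, was at 955 ± 339 against 3266 ± 723 TPM, 3.42-fold lower. The recovered reads behind miR-204-5p were 61 and 38 in the knockout libraries and 8539, 6710 and 2953 in the empty-vector libraries.

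The log2 change was -4.01 (SE 0.31, limma, BH-adjusted p = 4.81e-11) for miR-204-5p and -1.80 (SE 0.26, limma, BH-adjusted p = 5.09e-06) for miR-15b-5p, and both were lower in every knockout library than in any empty-vector library. Mir204 lies in an intron of Trpm3 on chromosome 19 at 22750605 to 22750672, and Mir15b in an intron of Smc4 on chromosome 3 at 69009772 to 69009835. The study chose these miRNAs, so their direction is not independent evidence.

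**Figure D2:**
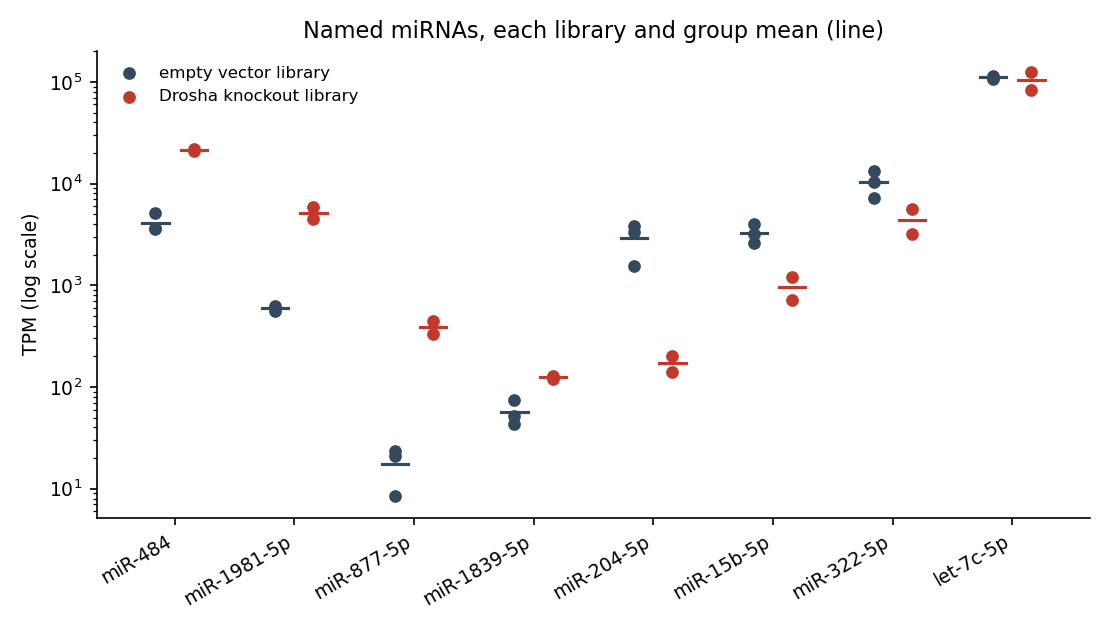
TPM on a log axis in each library (points) with group means (lines), for empty-vector and Drosha knockout libraries. miR-204-5p lay at 139 to 202 TPM in the knockout libraries and at 1558 to 3825 TPM in the empty-vector libraries.

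Over all 205 tested miRNAs, 57 were higher and 56 lower in the knockout, and 92 did not pass the threshold (limma, BH). Of those lower, 21 belonged to the Sfmbt2 list described below, whose members are near-identical copies that share reads. The counts are therefore not all of separate measurements. At a mean of at least 100 TPM, and apart from the Drosha-independent list, the largest rises included miR-2137 at 621 ± 41.2 against 45.6 ± 14.0 TPM (13.6-fold) and miR-3102-5p.2-5p at 252 ± 85.3 against 25.2 ± 8.90 TPM (10.0-fold; SD, n = 2 and n = 3). miR-5100 was at 1532 ± 1071 against 257 ± 140 TPM. Smaller rises were seen for miR-3470a (log2 change 2.18), miR-3068-5p (2.17), miR-1843b-5p (2.16) and miR-664-3p (1.92), of which the last 3 have hairpins that overlap an annotated snoRNA or scaRNA. Mir2137 lies in an intron of Zfp185 on chromosome X at 72992079 to 72992144, and Mir3102 within Arhgef17 on chromosome 7 at 100882306 to 100882409.

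Among miRNAs with a mean of at least 100 TPM and no overlap between the groups' libraries, to which the named rises and falls are limited, miR-378c was next after miR-204-5p among falls, at 570 ± 225 against 2309 ± 336 TPM, 4.05-fold lower. It is nearly identical in sequence to other miR-378 members, so its value is uncertain. The other named falls under this limit, besides miR-15b-5p, were miR-669o-5p (log2 change -1.88), miR-466c-5p (-1.75), miR-669l-5p (-1.72), miR-497a-5p (-1.40), miR-669b-5p (-1.37) and miR-669a-5p and miR-669p-5p (both -1.37), the last pair having identical values in all libraries. All of these except miR-497a-5p belong to the Sfmbt2 list. The adjusted p in limma with BH was 1.38e-09 for miR-2137, 3.48e-07 for miR-3102-5p.2-5p, 2.32e-05 for miR-5100 and 6.47e-07 for miR-378c.

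The split of higher against lower calls depended on scaling. It was 57 against 56 as deposited, with a median log2 change of -0.08, 42 against 81 under TMM (median -0.46), and 3 against 160 with libraries rescaled to an equal Drosha-independent sum (median -2.53). Under that last rescaling miR-3470a (-0.33), miR-3068-5p (-0.33), miR-1843b-5p (-0.33) and miR-664-3p (-0.58) turned negative, and the calls of miR-3102-5p.2-5p (0.81) and miR-5100 (0.064) were lost. The number lower dropped to 34 without knockout library 2 and to 34 without empty-vector library 1, and without knockout library 2 the calls of miR-5100 (1.80), miR-497a-5p (-1.05) and miR-669b-5p (-1.19) were lost. The call of miR-5100 was also lost under robust empirical Bayes (limma, BH-adjusted p = 0.0775).

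**Figure D3:**
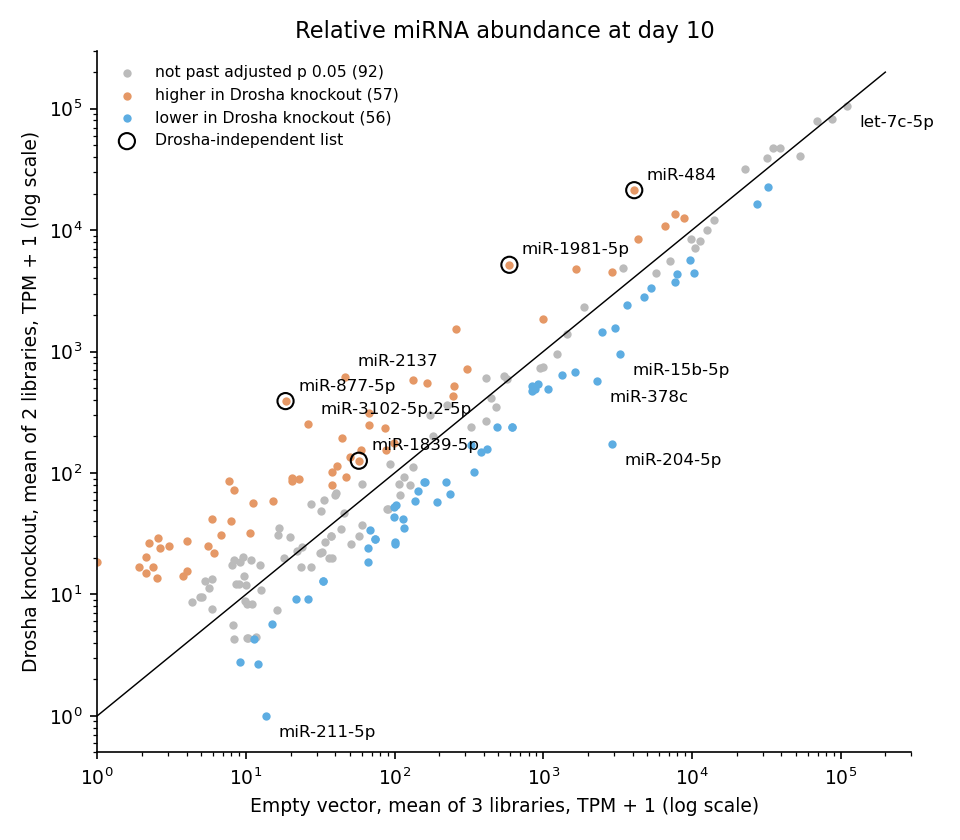
Mean TPM + 1 of each of the 205 tested miRNAs in the empty-vector (x axis) and Drosha knockout (y axis) groups on log axes, with the line of equality. Orange points are the 57 miRNAs called higher and blue points the 56 called lower as deposited (3 and 160 after rescaling to the Drosha-independent sum), and circles mark the Drosha-independent list.

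The 5 most abundant miRNAs of the empty-vector group did not pass the threshold as deposited. let-7c-5p was at 104411 ± 29363 TPM in the knockout and 110593 ± 4190 TPM in the empty-vector group, with a log2 change of -0.11 (limma, BH-adjusted p = 0.651). The log2 changes were -0.10 for let-7b-5p (adjusted p = 0.679), 0.15 for miR-181a-5p (adjusted p = 0.552), -0.38 for miR-99b-5p (adjusted p = 0.114) and 0.28 for let-7a-5p (adjusted p = 0.271). Under TMM rescaling miR-181a-5p (-0.23) and let-7a-5p (-0.10) were negative and miR-99b-5p passed (-0.77; -0.51 under quantile normalization), and without knockout library 2 let-7c-5p (0.18), let-7b-5p (0.0031) and miR-181a-5p (-0.16) changed sign. After rescaling to the Drosha-independent sum all 5 passed as lower, let-7c-5p at -2.63, let-7b-5p at -2.62, miR-99b-5p at -2.90, miR-181a-5p at -2.37 and let-7a-5p at -2.24. Of the TPM summed over 1 pair per mature miRNA, the 10 most abundant took 72.3% ± 0.465 in the knockout and 71.5% ± 1.04 in the empty-vector group (exact permutation p = 0.4). The share of the Drosha-independent list given above is of the full TPM sum over all pairs instead. At 1 TPM or more, 289 ± 2.83 miRNAs were listed in the knockout and 272 ± 12.8 in the empty-vector group (exact permutation p = 0.2). As 1 read in the knockout exceeds 1 TPM, this threshold is not the same in both groups, and above 0 TPM the difference was -40.3.

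The relatives of the miRNAs in the title moved unevenly. Both miR-204-5p and its list partner miR-211-5p were called lower. In the empty-vector libraries miR-211-5p had only 0.387% to 0.480% as many reads as miR-204-5p. Whether it is a separate measurement was not tested. miR-211-5p, which shares the seed of miR-204, had no read in the knockout libraries and 12.6 ± 6.03 TPM in the empty-vector group, at least 1.20-fold lower against the mean of the 3-read floors per library. Of 6 tested miR-15/16 family members, 4 fell and 2 did not pass. miR-322-5p was at 4430 ± 1758 against 10299 ± 3032 TPM (log2 change -1.23), and miR-503-5p (-1.83) and miR-497a-5p (-1.40) fell with miR-15b-5p. miR-16-5p, which has a copy beside miR-15b and another beside miR-15a, had a log2 change of -0.03 and miR-15a-5p one of 0.16.

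Adjusted over the list alone, 2 of 2 and 4 of 6 were lower, which is not independent evidence since the study chose members of both lists. The camera adjusted p was 0.0303 for miR-204 and miR-211 (adjusted p = 0.636 with an estimated correlation; median -3.83, or -2.13 with miR-211-5p at its bound) and 0.0917 for the miR-15/16 family (median -1.32). The list of miR-204 and miR-211 call was lost without knockout library 1 (median -3.96), knockout library 2 (-3.69) or empty-vector library 1 (-3.55) and under TMM (-4.09), quantile normalization (-3.92), Drosha-independent rescaling (-5.55), a pseudocount of 0.1 (-5.43) and thinning (-3.63). The miR-15/16 list passed without empty-vector library 3 (-1.58) and without a filter on low values (-1.40), and its adjusted p was 0.899 with an estimated correlation and all libraries. Without knockout library 2 the calls of miR-503-5p (-1.62), miR-322-5p (-0.82) and miR-497a-5p (-1.05) were lost.

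miRNAs described as acting on adipogenesis changed in both directions. Of 12 tested pro-adipogenic miRNAs, 5 rose, 3 fell and 4 did not pass. miR-17-5p (log2 change 1.51) and miR-20a-5p (1.39) rose, while miR-26b-5p (683 ± 233 against 1642 ± 179 TPM, -1.30) and miR-378a-5p (-1.06), the passenger arm of an energy-metabolism miRNA, fell. Of 12 anti-adipogenic miRNAs, 2 rose, 1 fell and 9 did not pass. No 3p arm was among these 12 and only 1 was among the 12 pro-adipogenic miRNAs. The counts may therefore in part concern passenger strands. miR-145a-5p was at 4806 ± 3229 against 1659 ± 592 TPM (1.41), miR-138-5p had a log2 change of 0.96 and miR-27a-5p one of -0.99.

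Adjusted over the list alone, 5 were higher and 3 lower in the pro-adipogenic list and 1 higher and 0 lower in the anti-adipogenic list. Neither list stood apart from other miRNAs (camera adjusted p = 0.782 for both), and their medians of 0.59 and 0.37 became -1.92 and -2.05 after rescaling to the Drosha-independent sum, where miR-17-5p (-0.97), miR-20a-5p (-1.10), miR-145a-5p (-1.11) and miR-138-5p (-1.51) were negative too. The anti-adipogenic median was also negative under quantile normalization (-0.29), and the pro-adipogenic one without a filter on low values (-0.22). Calls were lost without knockout library 2 for miR-17-5p (1.37), miR-20a-5p (1.23), miR-145a-5p (0.67), miR-27a-5p (-0.40) and miR-138-5p (0.62), without knockout library 1 for miR-378a-5p (-0.39) and miR-138-5p (1.30), without empty-vector library 1 for miR-378a-5p (-1.10), miR-145a-5p (1.15), miR-27a-5p (-0.90) and miR-138-5p (0.71), and without empty-vector library 3 for miR-378a-5p (-0.97), miR-27a-5p (-0.87) and miR-138-5p (1.05). After thinning to equal reads all 4 of miR-378a-5p, miR-145a-5p, miR-27a-5p and miR-138-5p lost their calls, miR-138-5p also under TMM (0.59), median of ratios (0.89) and quantile normalization (0.92), miR-27a-5p under quantile normalization (-1.22) and miR-145a-5p under robust empirical Bayes (limma, BH-adjusted p = 0.0865).

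The list for the clustered miRNAs of an intron of Sfmbt2, a rodent-specific array on chromosome 2, had the most falls of any list. Of 30 tested members, 21 fell, 9 did not pass and 0 rose, in limma with BH, and 22 were lower when adjusted over the list alone. The median log2 change was -1.19. The list was set by miRNA name, and miR-466k, among those called lower (-1.44), lies on chromosome 3 outside Sfmbt2. miR-669o-5p was at 65.6 ± 28.3 against 236 ± 53.4 TPM and miR-466c-5p at 101 ± 24.4 against 341 ± 51.2 TPM, while miR-466e-5p (-2.52) and miR-297c-5p (-2.03) were near the read floor. The camera adjusted p was 1.63e-05, but adjusted p = 0.636 with an estimated correlation. These miRNAs are near-identical copies that share reads, so they are not separate measurements and single members are uncertain. Calls were lost for miR-297c-5p without knockout library 2 (-0.56) and empty-vector libraries 1 (-2.09), 2 (-1.95) or 3 (-2.04), and for miR-466e-5p without empty-vector library 1 (-2.51) or 3 (-2.37). After thinning (-0.92) and with a pseudocount of 10 (-0.65) miR-297c-5p was not called.

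In the Dlk1-Dio3 cluster, an imprinted array on chromosome 12, 3 members of 48 listed were tested, and all 3 rose, also when adjusted over the list alone. miR-411-5p was at 88.2 ± 16.6 against 21.9 ± 6.16 TPM (log2 change 1.98), miR-369-5p had a log2 change of 2.27 and miR-379-5p one of 1.80. With empty-vector means of 4.52 and 2.80 TPM, miR-369-5p and miR-379-5p passed the filter of 5 TPM only through the knockout. Their knockout reads were 8 and 6 for miR-369-5p and 2 and 5 for miR-379-5p. That all 3 rose is therefore partly set by the filter. The list's median of 1.98 was not past the threshold (camera adjusted p = 0.212) and became -0.27 after rescaling to the Drosha-independent sum, with miR-411-5p at -0.47, miR-379-5p at -0.27 and miR-369-5p at 0.014, none of them called. The call for miR-379-5p was lost without knockout library 2 (1.13) and empty-vector libraries 1 (1.63), 2 (1.68) or 3 (2.09), under TMM (1.48), median of ratios (1.74) and quantile normalization (1.11), under robust empirical Bayes (limma, BH-adjusted p = 0.0518), with a pseudocount of 0.1 (2.11) and after thinning (2.69).

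**Figure D4:**
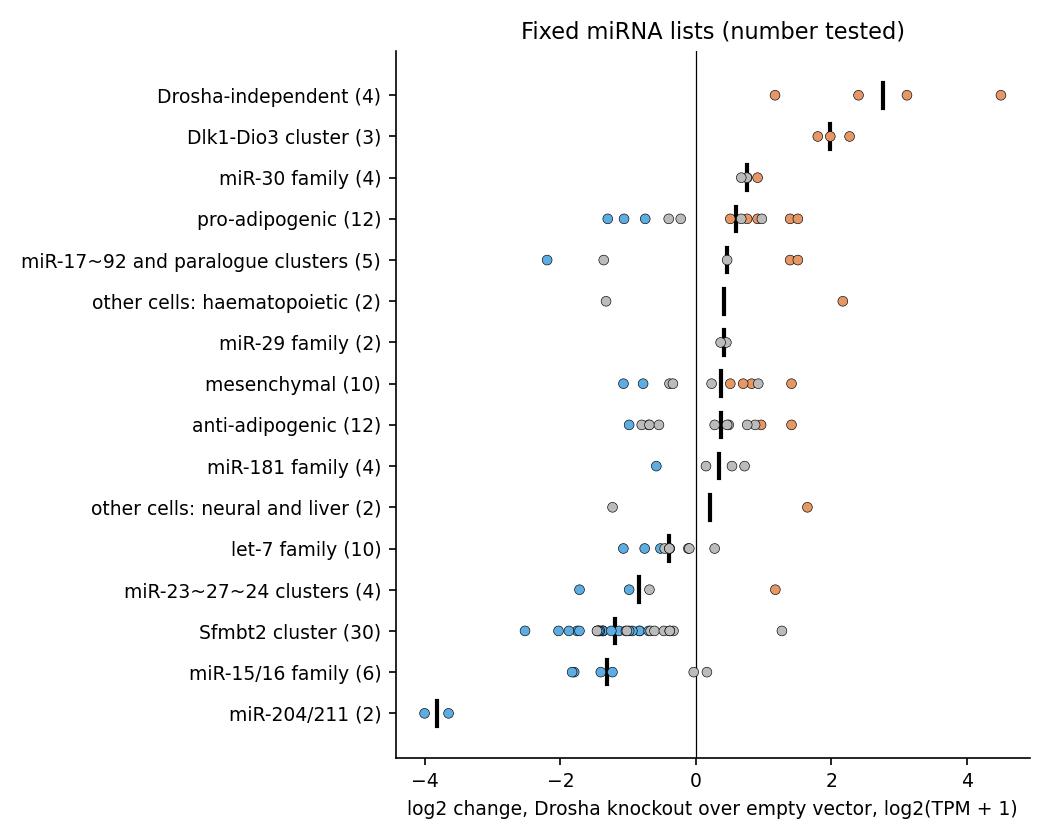
Log2 change of each tested member (points) of the fixed miRNA lists, with the list median (black bar) and the number tested in brackets. Orange points were called higher, blue lower and grey not; the medians run from -3.83 for miR-204 and miR-211 to 2.76 for the Drosha-independent list, and after rescaling to the Drosha-independent sum only the latter median stays above 0, at 0.24.

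The remaining families showed partial changes. In the let-7 family, 3 of 10 tested members fell, 7 did not pass and 2 were lower when adjusted over the list alone, with let-7e-5p at 3729 ± 1271 against 7663 ± 1130 TPM (log2 change -1.07), let-7f-5p at -0.76 and let-7i-5p at -0.52. In the miR-30 family, 2 of 4 rose, miR-30d-5p at 8463 ± 3838 against 4324 ± 873 TPM (0.91) and miR-30a-5p (0.76), and 4 were higher when adjusted over the list alone. Of 4 miR-181 members, miR-181b-5p fell (-0.58) and 3 did not pass, with 0 called over the list alone. Both tested miR-29 members, miR-29c-5p (0.37) and miR-29b-1-5p (0.45), are 5p arms that did not pass. Of 5 miR-17~92 and paralogue members, miR-17-5p and miR-20a-5p rose, miR-92a-1-5p fell (-2.20) and 2 did not pass. In the miR-232724 clusters, miR-23b-5p (-1.72) and miR-27a-5p (-0.99) fell and miR-24-2-5p rose (1.17), with 1 not past. In both of these lists the calls adjusted over the list alone had the same counts, and no 3p arm was tested.

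Of 10 mesenchymal miRNAs, 4 rose, 2 fell and 4 did not pass, and 4 and 2 also when adjusted over the list alone. miR-125b-5p was at 13676 ± 1434 against 7744 ± 928 TPM (0.82), while miR-99a-5p (-0.78) and miR-10a-5p (-1.07) fell. The call of miR-125b-5p was lost under TMM (0.44) and that of miR-10a-5p under quantile normalization (-0.78). The camera adjusted p was 0.246 for let-7 and miR-30, 0.892 for miR-181, 0.725 for miR-232724 and 0.782 for miR-29, miR-17~92 and the mesenchymal list. The miR-17~92 median was 0.46 and its mean -0.04. With an estimated correlation, 0 of the 16 tested lists passed, against 3 with the preset one. After rescaling to the Drosha-independent sum the medians of miR-30 (0.75), miR-29 (0.41), miR-181 (0.34), miR-17~92 (0.46) and the mesenchymal list (0.37) became -1.75, -2.07, -2.11, -2.06 and -1.94, miR-30d-5p (-1.61), miR-30a-5p (-1.75), miR-24-2-5p (-1.29), miR-125b-5p (-1.70), miR-29c-5p (-2.12) and miR-29b-1-5p (-2.02) were negative, and the let-7 list passed (-2.91).

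Several of these calls were lost when 1 library was left out, where fewer libraries also weaken the test. Without knockout library 2, let-7e-5p (-0.72), let-7f-5p (-0.63), let-7i-5p (-0.33), miR-30d-5p (0.43), miR-30a-5p (0.31), miR-92a-1-5p (-0.50), miR-24-2-5p (1.26) and miR-27a-5p (-0.40) were no longer called. Without empty-vector library 1 this held for let-7i-5p (-0.55), miR-30d-5p (0.74), miR-30a-5p (0.53), miR-92a-1-5p (-2.34), miR-24-2-5p (0.91) and miR-27a-5p (-0.90). It also held without knockout library 1 for miR-24-2-5p (1.09), without empty-vector library 2 for let-7i-5p (-0.39), and without empty-vector library 3 for miR-30a-5p (0.80), miR-92a-1-5p (-2.07) and miR-27a-5p (-0.87). miR-181b-5p lost its call without any 1 of the 5 libraries (-0.64 to -0.52) and under quantile normalization (-0.44). Over the libraries left out, the change of miR-24-2-5p ranged from 0.91 to 1.55 and that of miR-92a-1-5p from -3.89 to -0.50. Under TMM the calls of miR-30d-5p (0.53), miR-30a-5p (0.38) and miR-24-2-5p (0.80) were lost, and after thinning those of the same miRNAs, let-7i-5p and miR-92a-1-5p (-1.90). Quantile normalization also ended the calls of let-7i-5p (-0.34), miR-30a-5p (0.85) and miR-24-2-5p (1.10), and median of ratios that of miR-30a-5p (0.68).

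The listed arms of marker miRNAs of other cell types were scarce in both groups. No 3p arm of these lists was tested, and many 3p arms were not analysed here. The low sums therefore do not show that other cells were absent. Epithelial markers summed to 0 to 7.33 TPM per library, muscle markers to 0 to 11.5 TPM and endothelial markers to 0 to 3.67 TPM, and none of these was tested. Of 2 haematopoietic markers tested, the erythroid miR-451a was higher, at 39.3 ± 27.4 against 6.99 ± 1.73 TPM (log2 change 2.17, limma, BH-adjusted p = 0.00371). Of 2 neural and liver markers tested, miR-122-5p was higher, at 31.1 ± 7.65 against 9.63 ± 3.78 TPM (1.65, limma, BH-adjusted p = 0.0157). In each of these lists 1 was higher when adjusted over the list alone. The camera adjusted p was 0.782 for the haematopoietic list (median 0.42) and 0.892 for the neural and liver list (median 0.21). miR-451a is also known to mature without Dicer, from a hairpin cut by Drosha. The call of miR-451a was lost without knockout library 2 (1.41) and that of miR-122-5p without knockout library 1 (1.40) or empty-vector library 3 (1.30). That of miR-451a was also lost after thinning (2.69) and that of miR-122-5p under TMM (1.29) and quantile normalization (1.19), and both were negative after rescaling to the Drosha-independent sum (-0.17 and -0.72).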

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

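The direction and call of miR-204-5p and miR-15b-5p held under every alternative run, with log2 changes of -4.41 to -3.74 and -2.17 to -1.43 when each library was left out. The Drosha-independent list passed camera with the preset correlation under each alternative run, but not with an estimated correlation (adjusted p = 0.391), and its median was 0.24 after rescaling to its own sum, which that rescaling sets. The number higher was 31 at a mean of at least 50 TPM, where fewer miRNAs were tested, and 3 after Drosha-independent rescaling, which put 160 lower. The number lower was 36 with voom, 92 over every mature-precursor pair, where more were tested, and 34 to 52 when each library was left out; voom and the pairs were chosen after the data were seen. The negative-binomial count tests were planned for deposited counts and were not run on the reads recovered from the TPM. Depth limits the low miRNAs: 1 read in the knockout was worth over 3 TPM.

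Drosha-independent rescaling lowered every log2 change, by its construction, and reversed miR-484 (-0.12), miR-3470a (-0.33), miR-3068-5p (-0.33), miR-1843b-5p (-0.33), miR-664-3p (-0.58), miR-181a-5p (-2.37), let-7a-5p (-2.24), miR-1839-5p (-1.32), miR-17-5p (-0.97), miR-20a-5p (-1.10), miR-145a-5p (-1.11), miR-138-5p (-1.51), miR-29c-5p (-2.12), miR-29b-1-5p (-2.02), miR-30d-5p (-1.61), miR-30a-5p (-1.75), miR-24-2-5p (-1.29), miR-125b-5p (-1.70), miR-411-5p (-0.47), miR-379-5p (-0.27), miR-451a (-0.17) and miR-122-5p (-0.72). It also reversed the medians of the pro-adipogenic (-1.92), anti-adipogenic (-2.05), miR-17~92 (-2.06), miR-29 (-2.07), miR-30 (-1.75), miR-181 (-2.11), mesenchymal (-1.94), Dlk1-Dio3 (-0.27), haematopoietic (-1.55) and neural and liver (-2.03) lists. TMM reversed miR-181a-5p (-0.23), let-7a-5p (-0.10), miR-29c-5p (-0.012) and the miR-181 (-0.03) and neural and liver (-0.14) medians. Quantile normalization reversed the anti-adipogenic (-0.29), haematopoietic (-0.095) and neural and liver (-0.36) medians, no filter the pro-adipogenic one (-0.22), a pseudocount of 0.1 the haematopoietic one (-0.29) and every pair the neural and liver one (-1.23). For all but the first of these settings the cause was not tested.

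Over the libraries left out, let-7c-5p ranged from -0.40 to 0.18, let-7b-5p from -0.20 to 0.0031, miR-181a-5p from -0.16 to 0.46, and the medians of the miR-181 family from -0.060 to 0.74, of haematopoietic markers from -0.95 to 1.79 and of neural and liver markers from -0.22 to 0.64. The sign turned without knockout library 1 for neural and liver markers and without knockout library 2 for the others. The difference in miRNAs listed was 17.0 at 1 TPM, 28.0 at 10 TPM, 50.5 after thinning and -40.3 above 0 TPM. The share of the most abundant miRNA alone, of the TPM over 1 pair per mature miRNA, differed by -0.032 percentage points. Among other named miRNAs and lists, 23 calls were lost without knockout library 2, 15 without empty-vector library 1, 14 after thinning and 13 without a filter. The last were those of miR-378a-5p, miR-27a-5p, miR-138-5p, let-7i-5p, miR-92a-1-5p, miR-30d-5p, miR-30a-5p, miR-181b-5p, miR-24-2-5p, miR-379-5p, miR-466e-5p, miR-297c-5p and miR-122-5p. With voom the calls of miR-378a-5p, miR-27a-5p, miR-138-5p, let-7i-5p, miR-92a-1-5p, miR-30a-5p, miR-181b-5p, miR-466e-5p and miR-297c-5p were lost, and with a pseudocount of 0.1 those of miR-138-5p, let-7i-5p, miR-30a-5p, miR-379-5p and the list of miR-204 and miR-211.

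Replicate numbers 1 and 2 occur in both groups, but same-numbered libraries did not deviate together (correlations of -0.12 and -0.14). With the number as a block, 39 were higher and 35 lower; among named miRNAs and lists 11 calls were lost and 1 was gained, the miR-15/16 list (-1.58), and miR-351-5p passed too (-0.78).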

Other observations

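The clusters described next were picked after their values were seen. In the X-linked cluster of miR-322, miR-503, miR-351, miR-542 and miR-450, whose members restrain the cell cycle in several cell types, 5 of 6 tested members fell (limma, BH): besides miR-322-5p and miR-503-5p, these were miR-542-5p at 1555 ± 250 TPM (SD, n = 2) against 3058 ± 819 TPM (SD, n = 3), miR-450a-5p at 237 ± 1.99 against 489 ± 45.4 TPM, and miR-450b-5p with a log2 change of -1.83. miR-351-5p, on the same strand between them, had a log2 change of -0.51 (limma adjusted p = 0.0755). It passed under TMM (-0.89), under median of ratios (-0.59), after Drosha-independent rescaling (-3.03) and without empty-vector library 3 (-0.78). It also passed over every mature-precursor pair (limma adjusted p = 0.0419), with the log2 change still at -0.51. That setting enters miRNAs with several precursors repeatedly in the fit and the adjustment. The calls of miR-322-5p (-0.82), miR-503-5p (-1.62) and miR-542-5p (-0.78) were lost without knockout library 2, and that of miR-542-5p also without empty-vector library 1 (-0.86) and under quantile normalization (-0.64). All 6 were negative under every scaling tried. In the cluster of chromosome 17 inside Spaca6, let-7e-5p fell (-1.07; -0.72 and not called without knockout library 2), while miR-99b-5p (-0.38) and miR-125a-5p (-0.48) were not past the threshold as deposited and were under TMM (-0.77 and -0.87) and after Drosha-independent rescaling. miR-99b-5p also passed under quantile normalization (-0.51), and miR-125a-5p under median of ratios (-0.56) and without knockout library 2 (-0.72). Whether members of a cluster differ from each other was not tested.

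The comparison of recovered reads, the test of hairpin positions, the split at 100 TPM and the use of the planned leave-outs as a test of a deviating library were chosen after the results were seen. The Drosha-independent list took a 5.68-fold larger share of TPM in the knockout. With 1 pair per mature miRNA, reads of the list differed 1.24-fold between empty vector and knockout and other miRNA reads 7.35-fold. This could reflect a loss of Drosha-dependent miRNAs with the others kept. Total reads sequenced are not known here, so such a loss cannot be told apart from a rise of the list in libraries sequenced less deeply. Outside the list, hairpins in mirtron positions or overlapping snoRNAs or scaRNAs were called higher for 8 of 9 (the exception being miR-6516-5p) against 44 of 186 other placed hairpins (two-sided Fisher's exact p = 0.000119), and for 6 of 6 against 32 of 168 at an empty-vector mean of at least 5 TPM (p = 7.81e-05, Fisher's exact test), so bypass of Drosha may extend to them as a hypothesis. The first of these counts was 7 of 9 against 31 of 186 under TMM (Fisher's exact p = 0.000174), with exact p = 4.29e-05 under median of ratios and 0.00021 under quantile normalization. After rescaling to the Drosha-independent sum, which leaves 3 miRNAs higher, it was 1 of 9 against 1 of 186 (Fisher's exact p = 0.0904), with median log2 changes of -0.33 and -2.69 against 2.16 and -0.30 as deposited. Fisher's test treats hairpins as independent, but the 186 include Sfmbt2 copies that share reads. The 9 include the related miR-1843a-5p and miR-1843b-5p. They also include miR-677-5p, whose groups overlapped (23.2 and 158 TPM in the knockout libraries, 4.93, 28.9 and 24.8 TPM in the others). The p-values may therefore overstate the evidence.

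Below a mean of 100 TPM, 33 miRNAs were called higher and 21 lower as deposited, against 24 and 35 at 100 TPM or more. Below 100 TPM the split was 31 against 24 under median of ratios, but 27 against 31 under TMM, 23 against 29 under quantile normalization and 1 against 76 after rescaling to the Drosha-independent sum, so the excess of higher calls depended on scaling. It also depended on the filter, which used the mean of all libraries. miR-7091-5p, with no empty-vector read, was tested only through the knockout. Among other placed hairpins of any abundance, 44 of 186 were called higher, and 32 of 168 at an empty-vector mean of at least 5 TPM.

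miR-204-5p, which the study chose, had a log2 change of -4.01. A single deviating library is argued against as the whole cause, since the change was -3.74 at highest when each library was left out. Its seed relative miR-211-5p, from another chromosome, was at 0.387% to 0.480% of its reads in the empty-vector libraries and had none in the knockout, so its fall is only bounded and the pair cannot be ranked. Whether miR-211-5p is a separate measurement from miR-204-5p was not tested. A biological difference between the cells, such as less advanced differentiation in the knockout, may underlie the low miR-204-5p but was not tested.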
